A study of Mus musculus with 12 samples.

How the data were processed

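Processed tables of 12 libraries were used, 6 from the axonal and 6 from the somatodendritic compartment of cultured Smn knockdown motoneurons, grouped and numbered by the sample titles. Total RNA was extracted with a kit for very small samples, per the labels' protocols. The authors deposited FPKM values and their lower and upper confidence bounds for each gene, in the gene table layout of Cufflinks, per the file headers. Cufflinks 2.2.1, FastQC 0.10.1 and the genome build GRCm38 are named in the submitters' processing notes. The aligner's settings, the annotation release, the handling of reads with several matches and the strand of the reads are not given in the sources used here. FPKM is relative to each library's own total, so a library rich in mitochondrial or short non-coding RNA has lower FPKM for all other genes. The confidence bounds were not used. All values carried the status OK, so the planned filter on that status had nothing to remove and was not run.

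Each table listed 39174 genes, of which 22736 were protein coding. Of the gene IDs, 37604 (96.0%) were found in GENCODE M21, and 37597 of these lay on the same chromosome. Gene names, types and coordinates are those of the deposited tables, with starts given 1-based, and GENCODE M21 served for exon lengths.

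Libraries were scaled by median-of-ratios factors over the 5607 genes above 0 in all libraries. Genes with a mean FPKM of at least 1 over the 12 libraries were kept, which left 13914. Values were tested as log2(scaled FPKM + 1) with limma 3.58.1 in R 4.3.3, with a mean-variance trend and robust moderation, compartment as the only term, two-sided, and Benjamini-Hochberg adjustment at 0.05. Fold changes are on this scale, which understates the change of low genes. Gene lists with at least 5 tested members were tested with camera at a preset inter-gene correlation of 0.01, and again with an estimated correlation and with fry. The lists for endothelial (2 tested) and skeletal muscle markers (1 tested) were too small. The lists not called and not named in the results are glycolysis (camera adjusted p = 0.13), postsynaptic and dendritic (0.205), axonal transport motors (0.353), proteasome (0.497), chromatin regulators (0.614), splicing factors and hnRNPs (0.614), endoplasmic reticulum and secretory pathway (0.803) and cholesterol synthesis (0.931). Of these, the glycolysis, transport motor, proteasome and splicing lists were called lower with FPKM as deposited and with libraries rescaled to a common sum. The secretory list was called lower with the latter alone, and the postsynaptic list without a filter and without axonal replicates 1 and 2. Some symbols stand in more than one list.

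The genes named were set by a rule. It took 6 fixed genes (Smn1, Pls3, Ntrk2, Bdnf, Cacna1b and Actb), the 8 largest rises and falls among called, fully separated protein-coding genes with a mean of at least 5, and up to 2 called members of each list in the main direction and 1 in the other. The second part gave Fanci alone and the third gave none. The 5 protein-coding genes of smallest p in each direction after Fanci and the examples of each called list were chosen after their values were seen, as were the genes called over a list alone, the collagens, Polg and the motoneuron genes listed at 0.

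The share of FPKM in mitochondrially encoded genes and the number of genes at an FPKM of at least 1, both as deposited, were compared by exact two-sided permutation over 924 arrangements (Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, with figures by matplotlib 3.10.9). Depth was estimated from 2935 protein-coding genes with 1 transcript and over 1000 exonic bases. In values of up to 5 reads, between 60.7 and 65.4% lay within 0.02 of a whole number of reads, against 5.5% for simulated values without steps. FPKM steps depend on gene length, so no count test was run.

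The limma steps were tested on simulated data with the real genes, means and depths, with a dispersion chosen to bring the median SD of a gene (0.93) near the real one. In a simulated axonal against somatodendritic comparison of 13914 genes, 200 were changed, 50 by each fold. At 16-fold 74% were recovered, at 8-fold 36%, at 4-fold 8% and at 2-fold 0%, and 3 unchanged genes were called. All 59 recovered genes had the correct direction.

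The test, the rule, the lists and most alternatives were fixed before the data were examined. The alternatives were other scalings, pseudocounts of 0.1 and 5, other filters, the replicate number as a block, array weights, plain moderation, an exact rank-sum test, and each library left out. Alternatives chosen after the data were examined leave out axonal replicates 1 and 2, with or without somatodendritic replicate 4, or treat replicates 1 and 2 against 3 to 6 as batches.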

Results

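Total RNA was profiled from the axonal and the somatodendritic side of primary mouse motoneurons of the CD-1 background in which Smn had been knocked down. The neurons were grown in microfluidic chambers, where axons pass through narrow channels into a compartment separate from the cell bodies and dendrites. There were 6 axonal and 6 somatodendritic libraries, and no library of unperturbed neurons was analysed here. Each library came with a table of FPKM (read fragments per gene, divided by transcript length and by the mapped fragments of the library) for 39174 genes on the GRCm38 mouse genome build. The labels do not say whether the replicates were separate cultures, so p-values measure the spread between these samples, which may be technical.

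The libraries were shallow. In genes with a single transcript, FPKM times exon length moved in steps of 1 read, and the size of that step implied 729000, 376000, 218000, 330000, 304000 and 283000 reads for axonal replicates 1 to 6. For somatodendritic replicates 1 to 6 it implied 362000, 263000, 276000, 55000, 277000 and 256000 reads. Of 222 genes of the ribosome, proteasome, respiratory chain and translation machinery, 40 were listed at 0 in somatodendritic replicate 4 and between 0 and 4 in each other library. A value of 0 therefore shows only that a gene was listed at 0, and values per library are given for such genes. The step of 1 read, in FPKM times kilobases of exon, was 1.37 in axonal replicate 1 and 18.2 in somatodendritic replicate 4. Low values above 0 can thus rest on few reads. On the scale log2(scaled FPKM + 1), pairs of libraries correlated across genes with a median Pearson r of 0.69 within the axonal group, 0.754 within the somatodendritic group and 0.699 between the groups. The median SD of a gene between replicates was 0.918 in axonal and 0.902 in somatodendritic libraries. Axonal replicates 1, 4, 5 and 6 correlated on average at 0.721, 0.691, 0.668 and 0.696 with the other axonal libraries, below their 0.749, 0.701, 0.675 and 0.724 with the somatodendritic ones. Axonal replicates 2 and 3 and all 6 somatodendritic libraries correlated more with their own group.

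Replicates 1 and 2 of both compartments differed in make-up from replicates 3 to 6. Genes of short non-coding RNA classes (misc_RNA, snRNA, snoRNA and rRNA) held 5.61 to 8.68% of FPKM in axonal and 6.18 to 6.67% in somatodendritic replicates 1 and 2. In replicates 3 to 6 they held 12.9 to 22.01% and 15.67 to 20.89%. Values within these sets of replicates are therefore given beside the pooled ones. Axonal replicates 1 and 2 also listed 131 and 278 of 1433 olfactory and vomeronasal receptor genes above 0, against 0 to 11 in the other libraries.

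Smn1, the knockdown target, was listed at 8.93, 17.5, 0, 7.58, 56.2 and 6.29 scaled FPKM in axonal replicates 1 to 6. In somatodendritic replicates 1 to 6 it was listed at 4.28, 0, 0, 0, 15.6 and 0. Without unperturbed libraries these values do not check the knockdown. The axonal minus somatodendritic log2 fold change of Smn1 was 2.15 ± 0.92 (SE, n = 6 per group), which did not pass the limma test (Benjamini-Hochberg adjusted p = 0.52).

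The series title concerns Plastin 3, the BDNF receptor TrkB and calcium homeostasis, and genes of these subjects were fixed for a report whatever their result. None passed the limma test, and the low values above 0 of Pls3 and Bdnf can rest on few reads. Pls3, which encodes the actin-bundling protein Plastin 3, lies on chromosome X from 75785654 to 75875182 and was listed at 10.1, 16.6, 14.7, 7.24, 0 and 6.04 scaled FPKM in axonal replicates 1 to 6. Its somatodendritic values were 2.08, 4.21, 1.91, 0, 1.89 and 1.97 (log2 fold change 1.47 ± 0.67 SE, limma adjusted p = 0.544). Bdnf, the neurotrophin that TrkB binds, on chromosome 2 from 109674700 to 109727007, was listed between 1.26 and 5.65 in all 6 axonal libraries. In the somatodendritic libraries it was listed at 1.12 and 1.03 in replicates 1 and 3 and at 0 in the others (log2 fold change 1.65 ± 0.45 SE, limma adjusted p = 0.372). Ntrk2, which encodes TrkB, stood at 39.1 ± 20.4 scaled FPKM in axonal and 30.3 ± 7.75 in somatodendritic libraries (SD, n = 6 each; limma adjusted p = 0.834). Cacna1b, the pore-forming subunit of the N-type calcium channel, stood at 29.3 ± 11.2 and 27.5 ± 7.16 (SD, n = 6 each; limma adjusted p = 0.973). Actb, which encodes beta-actin, stood at 1820 ± 272 and 1607 ± 332 (SD, n = 6 each; limma adjusted p = 0.732). The log2 fold changes of Ntrk2, Cacna1b and Actb were 0.25, 0.05 and 0.20, and with FPKM as deposited they turned to -0.0022, -0.20 and -0.06 (limma), so no direction is given for these genes.

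The main comparison asked which RNAs differ between the axonal and the somatodendritic side of Smn-depleted motoneurons. Of 13914 genes tested, 1 was called at an adjusted p below 0.05, and it was higher in axonal libraries. This gene was Fanci (ENSMUSG00000039187), which encodes a protein of the Fanconi anaemia DNA repair pathway and lies on chromosome 7 from 79391929 to 79450265. Fanci was listed at 6.59, 302.9, 196.3, 139.8, 367.7 and 149.3 scaled FPKM in axonal replicates 1 to 6 and at 0 to 0.98 in the somatodendritic libraries (log2 fold change 6.55 ± 0.74 SE, n = 6 per group, limma adjusted p = 0.00244). The 3' end of Fanci overlaps Polg, the mitochondrial DNA polymerase gene (79448791 to 79466362), and the strand of the reads is not given in the sources used here. Polg was listed between 8.4 and 27.3 in axonal libraries, and between 7.73 and 28.9 in somatodendritic libraries except replicates 4 and 6, at 0. No gene was called lower in axonal libraries. At an unadjusted p below 0.05, limma passed 1239 genes. The exact rank-sum test passed 1063 at that level and called 0. Its smallest possible p is 0.00216, so it could call no gene unless it called at least 603 together. The groups did not overlap for 99 genes, where chance gives 30.

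The count of called genes rested on which libraries were used. It was 11 without axonal replicate 6, 3 without axonal replicate 1, 2 without axonal replicate 2 and 2 without axonal replicate 4. Without axonal replicates 1 and 2 it was 7. Within replicates 3 to 6 it was 7, of which 3 were higher and 4 lower in axonal libraries. Within replicates 1 and 2 it was 0. With a term for these sets of replicates it was 6, of which 2 were higher and 4 lower. Fanci was among the calls in each of these fits except the one within replicates 1 and 2.

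The genes of smallest p after Fanci, chosen after their values were seen, did not pass the test. Among protein-coding genes with larger values in axonal libraries, Thbs1, which encodes the matrix glycoprotein thrombospondin 1, stood at 74.7 ± 59.3 scaled FPKM against 6.25 ± 2.73 (SD, n = 6 each; limma adjusted p = 0.0546). Cald1, which encodes the actin-binding protein caldesmon, stood at 42.8 ± 25.1 against 5.75 ± 3.96 (SD, n = 6 each; limma adjusted p = 0.147). S100a11, a calcium-binding protein gene, was listed between 5.97 and 89.6 in axonal and between 0 and 8.24 in somatodendritic libraries (limma adjusted p = 0.122). Hbb-y, an embryonic haemoglobin gene, was listed between 1.4 and 23.1 in axonal libraries and at 0 in all 6 somatodendritic ones (limma adjusted p = 0.0691). 1500015O10Rik was listed between 3.08 and 20.3 in axonal libraries and likewise at 0 in all 6 somatodendritic ones (limma adjusted p = 0.0546). Without axonal replicate 6, Thbs1, S100a11, Cald1 and 1500015O10Rik passed the test, at limma adjusted p of 0.00557, 0.00557, 0.0347 and 0.0481. Without axonal replicate 1, Hbb-y and 1500015O10Rik passed it, at 0.0318 and 0.0434. With a term for replicates 1 and 2 against 3 to 6, 1500015O10Rik passed it at 0.0261, and within replicates 3 to 6 alone it did not.

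Among those with smaller values in axonal libraries, Crmp1, a cytoskeletal regulator of neurite growth, stood at 346.2 ± 48.9 scaled FPKM against 567.1 ± 62.5 (SD, n = 6 each; limma adjusted p = 0.165). Vamp2, which encodes the synaptic vesicle SNARE synaptobrevin 2, stood at 186.4 ± 56.7 against 354.2 ± 77.4 (limma adjusted p = 0.315). With a term for replicates 1 and 2 against 3 to 6, Vamp2 passed the test, with a log2 fold change of -0.95 (limma adjusted p = 0.0261), and within replicates 3 to 6 alone Vamp2 did not (limma adjusted p = 0.204). Basp1, a growth cone membrane protein gene, stood at 169.2 ± 25.8 against 273.1 ± 33.3 (limma adjusted p = 0.315). Gabarapl1, an autophagy gene, stood at 92.6 ± 13.8 against 156.6 ± 22.4, and Ddx25, an RNA helicase gene, at 11.9 ± 4.93 against 30.3 ± 9.23 (SD, n = 6 each; limma adjusted p = 0.315 for both).

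**Figure D1:**
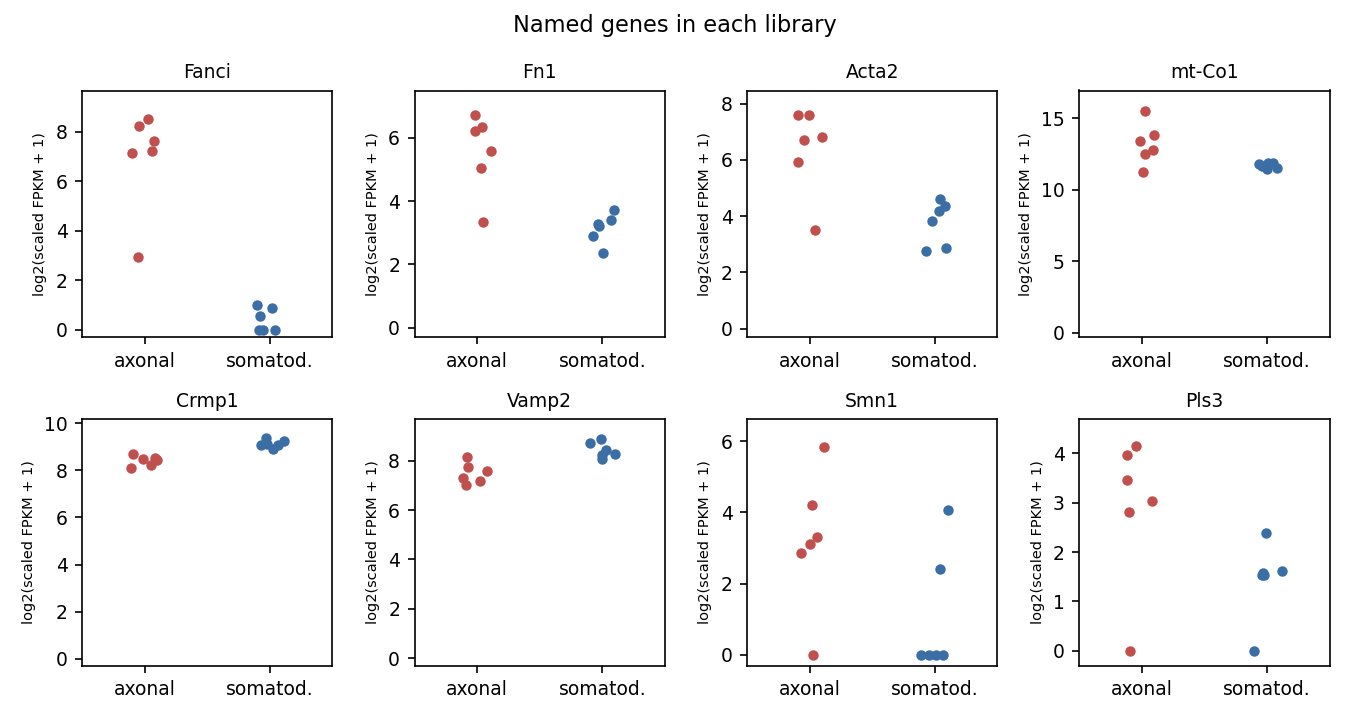
Scaled FPKM of 8 named genes in each library, as log2(scaled FPKM + 1) on the vertical axis, with 6 axonal (red) and 6 somatodendritic (blue) points per gene. Fanci passed the limma test (adjusted p = 0.00244) and the other 7 genes did not.

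Of 32 gene lists fixed before the data were examined, 30 had at least 5 tested members, and camera with a preset inter-gene correlation of 0.01 called 13 of them, 8 higher and 5 lower in axonal libraries relative to the other genes. The median log2 fold change of all tested genes was 0.18, and list medians are given relative to it. More genes therefore lay above 0 than below, and a count of members above 0 is not by itself a difference from other genes. Among lists not called, such counts ran from 6 of 18 (glycolysis) to 17 of 22 (cholesterol synthesis). With FPKM as deposited the median of all tested genes was 0.001, a shift of -0.179. With libraries rescaled to a common sum the shift was -0.248, with quantile normalization -0.214 and without somatodendritic replicate 4 -0.142. The 13 lists kept their direction under each of these settings. The nuclear-retained non-coding RNA list lost its call in all of them, and the immediate early and p53 lists lost theirs without somatodendritic replicate 4. With FPKM as deposited 5 further lists were called and with libraries rescaled to a common sum 7, all lower in axonal libraries. With an estimated correlation no list was called (lowest adjusted p = 0.203). The fry test, which asks whether a list moves on balance one way from 0 and not relative to other genes, called none (lowest adjusted p = 0.053). No list member was called over all genes, and 10 were called when p was adjusted over the list alone.

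Ribosomal protein messages were higher in axonal libraries. Of 81 cytosolic ribosomal protein genes, 76 had a log2 fold change above 0, with a median 0.42 above that of all genes (camera adjusted p = 8.19e-09, adjusted p = 0.444 with an estimated correlation). Within replicates 1 and 2 the median lay 0.64 above and within replicates 3 to 6 it lay 0.40 above. Rpl35 stood at 358.1 ± 170.5 scaled FPKM in axonal against 171.5 ± 43.5 in somatodendritic libraries, and Rpl18 at 50.3 ± 15.3 against 21.1 ± 10.02 (SD, n = 6 each). Translation factors were not called (camera adjusted p = 0.695), except lower with libraries rescaled to a common sum (camera adjusted p = 0.0211).

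Mitochondrially encoded RNA was higher in axonal libraries. All 13 mitochondrially encoded protein genes had a log2 fold change above 0, with a median 1.15 above that of all genes (camera adjusted p = 5.68e-07, adjusted p = 0.444 with an estimated correlation). The median lay 1.65 above within replicates 1 and 2 and 0.89 above within replicates 3 to 6. The rise within replicates 1 and 2 rests on axonal replicate 2. On the log2(scaled FPKM + 1) scale, the list's median was 9.82 in axonal replicate 1 and 14.07 in axonal replicate 2. In somatodendritic replicates 1 and 2 it was 9.87 and 9.73. The cytochrome c oxidase subunit gene mt-Co1, from 5328 to 6872 on the mitochondrial genome, stood at 2419 scaled FPKM in axonal replicate 1 and between 5773 and 45080 in the other axonal libraries. In somatodendritic libraries it stood at 3306 ± 368 (SD, n = 6). Over all genes mt-Co1 passed the limma test without axonal replicates 1 and 2 (adjusted p = 0.0353), a fit chosen after the data were examined. Nuclear-encoded genes of oxidative phosphorylation were not called (74 tested, camera adjusted p = 0.652).

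The share of FPKM in all mitochondrially encoded genes, rRNA and tRNA included, was 25.4 ± 15.0% in axonal and 11.1 ± 0.59% in somatodendritic libraries (SD, n = 6 each; exact two-sided permutation p = 0.0152). With libraries paired by replicate number it did not pass (exact sign-flip p = 0.0625), and whether the numbers pair the samples is not known. The axonal libraries held 9.71, 53.5, 20.5, 24.5, 26.4 and 17.6%, so that 5 of 6 lay above every somatodendritic library and replicate 1 below all of them. Without axonal replicate 2, whose share was the highest, the difference of 14.3 percentage points became 8.68 (exact permutation p = 0.0152). Within replicates 3 to 6 the shares were 22.2 ± 3.96% and 10.7 ± 0.18% (SD, n = 4 each; exact permutation p = 0.0286, the smallest that 70 arrangements allow). Within replicates 1 and 2 they were 9.71 and 53.5% against 11.6 and 12.0%, in a design of 6 arrangements that cannot reach p below 0.05. The total includes the gene Gm26924, which held 7.6 to 30.9% of FPKM in axonal and 25.7 to 37.9% in somatodendritic libraries. Of protein-coding FPKM alone, the mitochondrially encoded protein genes held 4.74 to 39.6% in axonal and 5.72 to 9.13% in somatodendritic libraries.

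The number of genes at an FPKM of at least 1 did not differ beyond the spread between replicates. It was 12532 ± 1270 in axonal and 11150 ± 1912 in somatodendritic libraries (SD, n = 6 each; exact two-sided permutation p = 0.186). Somatodendritic replicate 4 had 7273 such genes, and without it the difference of 1382 genes became 606.5 (exact permutation p = 0.357). Without axonal replicates 1 and 2 it became 638.2, and without these and somatodendritic replicate 4 it turned to -137.3 (exact permutation p = 0.81 and 0.651). Within replicates 3 to 6 the means were 11788.5 and 10648, and within replicates 1 and 2 they were 14020 and 12154.5.

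**Figure D2:**
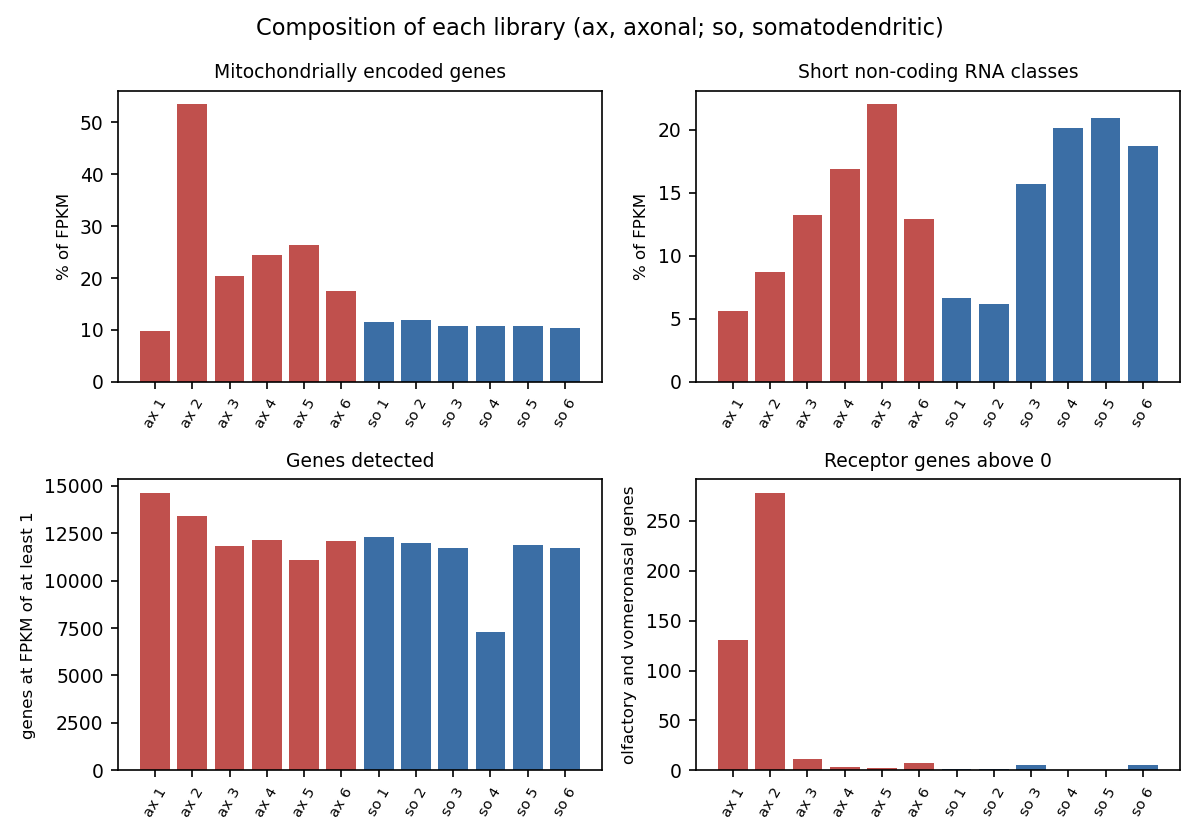
Make-up of each of the 6 axonal (red) and 6 somatodendritic (blue) libraries, as the percent of FPKM in mitochondrially encoded genes and in short non-coding RNA classes, the number of genes at an FPKM of at least 1, and the number of receptor genes above 0. The mitochondrial share lies between 10.4 and 12.0% in somatodendritic libraries and between 9.71 and 53.5% in axonal ones.

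The microtubule, calcium and presynaptic lists were called lower in axonal libraries relative to other genes, with libraries that overlapped between the groups. Of 48 microtubule and neurofilament genes, 33 had a log2 fold change below 0, with a median relative to all genes of -0.38 (camera adjusted p = 3.02e-04, adjusted p = 0.203 with an estimated correlation). It was -0.58 within replicates 1 and 2 and -0.30 within replicates 3 to 6. Dpysl2, which encodes the tubulin-binding protein CRMP2, stood at 138.2 ± 13.8 scaled FPKM in axonal and 202.0 ± 6.05 in somatodendritic libraries (SD, n = 6 each). The beta-tubulin gene Tubb5 stood at 530.2 ± 101.2 against 800.0 ± 163.9 (SD, n = 6 each). The actin cytoskeleton list was not called (53 tested, camera adjusted p = 0.914).

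Of 64 genes of calcium channels and calcium handling, 40 had a log2 fold change below 0, with a relative median of -0.39 (camera adjusted p = 0.00185, adjusted p = 0.203 with an estimated correlation). On the log2(scaled FPKM + 1) scale, the list's median in axonal replicate 1, 4.22, lay above that of every somatodendritic library (highest 4.13). The relative median was -0.45 within replicates 1 and 2 and -0.31 within replicates 3 to 6, where the list was no longer called. The relative medians of the microtubule and calcium lists were -0.24 and -0.19 without axonal replicates 1 and 2 and somatodendritic replicate 4. The kinase subunit gene Camk2g stood at 14.9 ± 2.95 scaled FPKM against 29.5 ± 2.78, and the neuronal calcium sensor gene Vsnl1 at 78.8 ± 30.7 against 148.8 ± 37.5 (SD, n = 6 each). Of 52 presynaptic genes, 29 had a log2 fold change below 0, with a relative median of -0.25 (camera adjusted p = 0.0027, adjusted p = 0.444 with an estimated correlation). It was -0.57 within replicates 1 and 2 and -0.31 within replicates 3 to 6. The list's median in axonal replicates 1 and 6, at 4.997 and 4.877, lay above that of every somatodendritic library (highest 4.744), and that of 2 other axonal libraries lay below them all. Vamp2 was the 1 member called when p was adjusted over the list alone. The small GTPase gene Rab3a of synaptic vesicles stood at 233.7 ± 29.97 scaled FPKM against 349.5 ± 75.9 (SD, n = 6 each).

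Markers of other cell types went different ways. Of 10 tested fibroblast and meningeal markers, 9 had a log2 fold change above 0, with a relative median of 1.03 (camera adjusted p = 1.50e-04, adjusted p = 0.203 with an estimated correlation). It was 2.01 within replicates 1 and 2 and 1.58 within replicates 3 to 6. Adjusted over the list alone, 5 members were called, all higher in axonal libraries. These were Fn1 (fibronectin), Acta2 (smooth muscle actin), Tagln (the smooth muscle actin-binding protein transgelin), Sparc and Col6a1 (matrix proteins). Fn1 stood at 57.6 ± 34.9 scaled FPKM against 8.22 ± 2.77, with 9.18 in axonal replicate 6, and Acta2 at 111.1 ± 71.8 against 14.2 ± 7.15 (SD, n = 6 each). Acta2 stood at 10.3 in axonal replicate 4. Over all genes, Fn1 passed the limma test without axonal replicate 6 (adjusted p = 0.00557) and Acta2 without axonal replicate 4 (adjusted p = 0.0115). The fibrillar collagen genes of the same list were low in the axonal libraries, with Col1a1 between 0 and 6.71, Col1a2 between 0 and 0.69 and Col3a1 between 0 and 0.66. In somatodendritic libraries Col1a1 stood at 2.9 in replicate 4 and at 0 in the others, and Col1a2 and Col3a1 stood at 0 in all.

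Of 12 astrocyte markers, 9 had a log2 fold change below 0, with a relative median of -0.60 (camera adjusted p = 0.0451, adjusted p = 0.54 with an estimated correlation). It was -0.88 within replicates 1 and 2 and -0.18 within replicates 3 to 6, and the list was called in neither set. The call was also lost without any one of axonal replicates 1, 4, 5 and 6 and somatodendritic replicates 1, 2, 3 and 6 (adjusted p up to 0.385). The list's median in axonal replicate 3, 4.28, lay above that of every somatodendritic library (highest 4.25). Atp1b2, a subunit of the sodium pump, stood at 77.9 ± 36.6 scaled FPKM against 110.4 ± 19.8 (SD, n = 6 each). Of 13 interneuron and sensory neuron markers, 9 had a log2 fold change below 0, with a relative median of -0.36 (camera adjusted p = 0.0333, adjusted p = 0.444 with an estimated correlation). It was -1.25 within replicates 1 and 2 and -0.16 within replicates 3 to 6, where the list was not called. It was also lost without any one of axonal replicates 2, 4 and 5 and somatodendritic replicates 1 and 2 (adjusted p up to 0.212). The relative medians of the astrocyte and interneuron lists were -0.30 and -0.24 without axonal replicates 1 and 2, and neither list was called there. The interneuron list's median in axonal replicate 6, 4.73, lay above that of every somatodendritic library (highest 4.71). The transcription factor gene Lmx1b stood at 11.8 ± 3.88 scaled FPKM against 29.7 ± 15.3, and the inhibitory vesicular transporter gene Slc32a1 at 22.2 ± 14.5 against 38.5 ± 11.5 (SD, n = 6 each). Microglia and blood cell markers (camera adjusted p = 0.637) and Schwann cell and oligodendrocyte markers (camera adjusted p = 0.931) were not called. Their relative medians were 0.036 and 0.0062 over all libraries, 0.44 and 0.07 within replicates 3 to 6, and -0.74 and -0.68 within replicates 1 and 2. Without axonal replicates 1 and 2 they were 0.76 and 0.49, and the microglia and blood list was called higher (camera adjusted p = 0.0193), as it was without these libraries and somatodendritic replicate 4 together (relative median 0.90, camera adjusted p = 0.0207).

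The cell cycle and histone lists were called higher in axonal libraries relative to other genes, with libraries that overlapped between the groups. The list's median lay above that of every somatodendritic library in 2 axonal libraries for cell cycle genes and in 3 for histones. Of 39 cell cycle genes, 30 had a log2 fold change above 0, with a relative median of 0.71 (camera adjusted p = 0.00627, adjusted p = 0.54 with an estimated correlation). The proliferation marker gene Mki67 stood at 10.6 ± 9.82 scaled FPKM against 2.75 ± 2.26 (SD, n = 6 each), and the axonal mean was 7.0 without axonal replicate 3, at 28.6. Without axonal replicate 3 this list was not called (adjusted p = 0.105). Of 49 replication-dependent histone genes, 37 had a log2 fold change above 0, with a relative median of 0.27 (camera adjusted p = 0.0251, adjusted p = 0.711 with an estimated correlation). The call was lost without any one of axonal replicates 4 and 5 and somatodendritic replicates 1 and 2 (adjusted p up to 0.326). These genes are near-identical copies whose reads the counting could split, so single members are uncertain. Hist1h2be, for example, stood at 7.45 ± 5.59 scaled FPKM against 0.99 ± 0.87 (SD, n = 6 each), and the somatodendritic mean was 0.639 without somatodendritic replicate 6. Within replicates 1 and 2 the relative medians of these lists were 0.35 and 0.22, and within replicates 3 to 6 they were 0.46 and 0.36. The relative median of the histone list was 0.69 without axonal replicates 1 and 2, and 0.76 also without somatodendritic replicate 4. Neither list was called within replicates 1 and 2 or without a filter on low values.

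Of 18 immediate early genes, 16 had a log2 fold change above 0, with a relative median of 0.43 (camera adjusted p = 0.0271, adjusted p = 0.444 with an estimated correlation). Homer1 stood at 24.5 ± 22.5 scaled FPKM against 7.69 ± 2.64 (SD, n = 6 each), and the axonal mean was 15.7 without axonal replicate 2, at 68.6. Of 20 p53 targets, 15 had a log2 fold change above 0, with a relative median of 0.32 (camera adjusted p = 0.0451, adjusted p = 0.474 with an estimated correlation). Ccng1, a cyclin gene, stood at 22.9 ± 11.8 against 10.9 ± 4.22 (SD, n = 6 each). Of 15 nuclear-retained non-coding RNAs, 11 had a log2 fold change above 0, with a relative median of 0.28 (camera adjusted p = 0.0451, adjusted p = 0.444 with an estimated correlation). Malat1 stood at 959.3 ± 331.6 scaled FPKM against 501.7 ± 100.9 and Gas5 at 72.1 ± 13.7 against 35.4 ± 12.7 (SD, n = 6 each), and these and Meg3 were called, all higher, when adjusted over the list alone. Nuclear retention was taken from the list and was not tested here, for Gas5 or any other member. Within replicates 3 to 6 the relative medians of these lists were 0.33, 0.43 and 0.32, and within replicates 1 and 2 they were 1.00, 0.04 and 0.09. They were 0.29, 0.50 and 0.53 without axonal replicates 1 and 2, where the immediate early and p53 lists were not called and the nuclear-retained list was. None of the immediate early, p53 and nuclear-retained lists was called within replicates 3 to 6, and of these only the immediate early list was called within replicates 1 and 2. With 1 library left out, the immediate early list was lost without axonal replicate 1 or 6 or somatodendritic replicate 1, 3 or 4 (adjusted p up to 0.0751). The p53 list was lost without axonal replicate 1, 3, 4 or 5 or somatodendritic replicate 1, 2, 3 or 4 (up to 0.23). The nuclear-retained list was lost without axonal replicate 1, 4, 5 or 6 or somatodendritic replicate 1, 2, 3, 4 or 5 (up to 0.169).

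**Figure D3:**
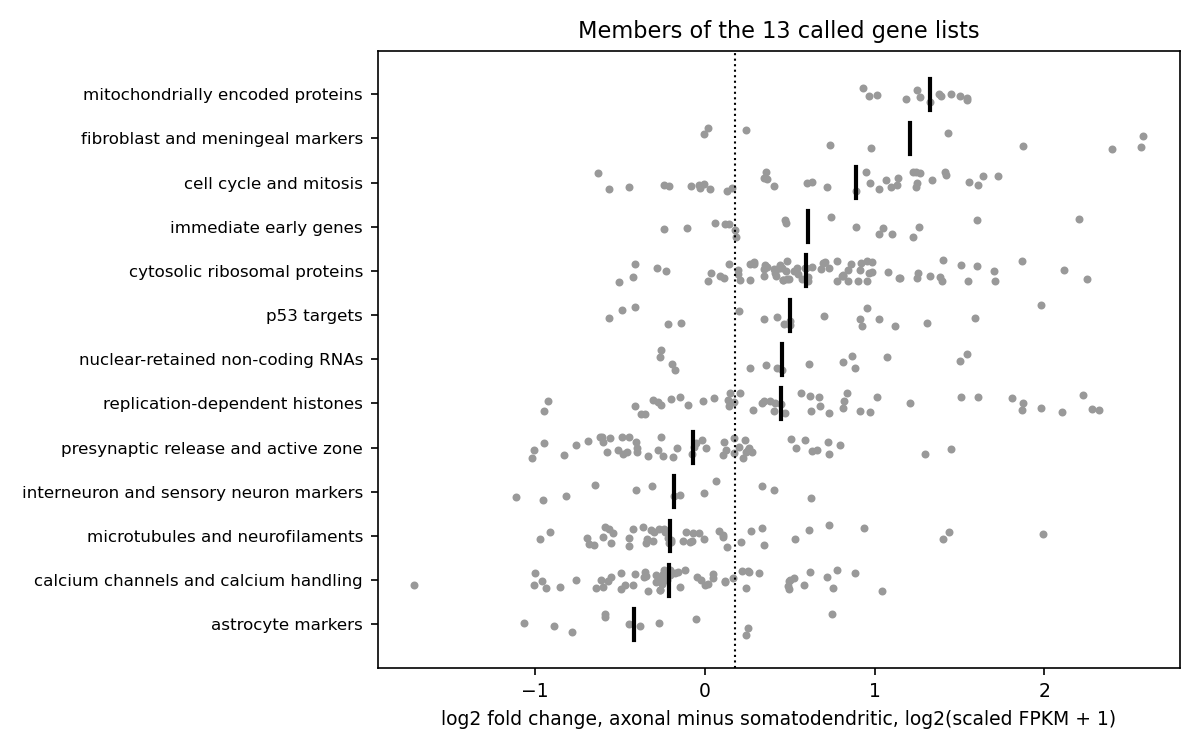
Log2 fold change, axonal minus somatodendritic on the log2(scaled FPKM + 1) scale, of each tested member (grey points) of the 13 called gene lists, with the list median (black bar) and the median of all tested genes, 0.18 (dotted line). The 8 lists called higher have medians to the right of the dotted line and the 5 called lower to the left.

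The other 17 lists were not called (camera adjusted p from 0.13 to 0.931). The TrkB/BDNF and neurotrophin signalling list had a median 0.0035 above that of all genes (50 tested, camera adjusted p = 0.652). The SMN complex and snRNP core list had a relative median of -0.14 (26 tested, camera adjusted p = 0.614). Its member Snrpn, a small nuclear ribonucleoprotein gene, was called when adjusted over the list alone, with a log2 fold change of -0.71 (limma adjusted p = 0.0482). mRNAs known from the literature to localize to axons were not called either (33 tested, relative median -0.19, camera adjusted p = 0.279), but were called lower with FPKM as deposited and with libraries rescaled to a common sum (camera adjusted p = 0.0319 and 0.0211). Of 25 motoneuron identity genes, 13 passed the filter on low values, and the list was not called (camera adjusted p = 0.614). Chat, Mnx1, Calcb and Uts2b were listed at 0 in all 12 libraries, Slc5a7 at 0 in 10 of them, and Isl1 and Prph at 0 in 8. On the log2(scaled FPKM + 1) scale, the list's median per library ran from 0 to 2.91. That of the interneuron and sensory neuron list ran from 3.02 to 4.73. The lists hold different genes, and the share of each cell type was not measured. In 11 of these 17 lists the median and the mean log2 fold change, both set against 0, and the direction of the test did not all share a sign. The test is relative to other genes, and the median of all tested genes was 0.18, so such a difference need not be a conflict.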

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

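Of 86 groups of 6 libraries, over the reported library measures and the named genes, 8 held a library far from the others of its group, where chance gives about 1 in 20. Somatodendritic replicate 4 had 7273 genes at an FPKM of at least 1, against 11720 to 12308 in the other 5 somatodendritic libraries. It also stood apart for Atp1b2, at 71.7 scaled FPKM against 111.7 to 128.6. Axonal replicate 2 stood apart for mt-Co1, at 45080 scaled FPKM against 2419 to 14310 in the other 5 axonal libraries, and for Homer1, at 68.6 against 10.2 to 27.5. Replicate 5 of both compartments stood apart for Smn1, at 56.2 scaled FPKM against 0 to 17.5 in the axonal group and at 15.6 against 0 to 4.28 in the somatodendritic group. Perp stood at 5.97 in somatodendritic replicate 5 against 0 to 1.09, and Hist1h2be at 2.74 in somatodendritic replicate 6 against 0.483 to 0.796.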

How the results depend on the processing

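The fits on subsets of replicates 1 and 2 or 3 to 6, and the batch term, were chosen after the data were examined. The count of called genes, 1 in the report, was 1 with FPKM as deposited, rescaled to a common sum, quantile normalized, with a pseudocount of 5, without a filter and at a mean FPKM of at least 5. It was 3 with a pseudocount of 0.1, 5 with array weights and 3 with plain moderation, all higher in axonal libraries, and 0 with the exact rank-sum test, which could call genes only 603 or more together, so that its 0 says nothing about the call of Fanci. Leaving out 1 library gave 1 to 11 genes, all higher. Without axonal replicates 1 and 2 it was 7, all higher, and also without somatodendritic replicate 4 it was 5, 4 higher and 1 lower. The batch term gave 6, 2 higher and 4 lower, replicates 3 to 6 gave 7, 3 higher and 4 lower, and replicates 1 and 2 gave 0. The cause was not tested. The replicate block gave 5 genes, 3 higher and 2 lower. Deviations of same-numbered libraries correlated at 0.242, 0.0461, 0.02, 0.00936, 0.0712 and -0.000451, and 3 of 6 axonal libraries correlated best with their own number. The labels do not say whether the numbers pair the samples, and these values leave that open. The count of called lists, 13 in the report, was 9 to 19 under the other planned settings except 7 without a filter, 0 with an estimated correlation and 0 with fry. Leaving out 1 library gave 7 to 12 lists, 7 without somatodendritic replicate 1 and 8 without axonal replicate 4, axonal replicate 5 or somatodendritic replicate 2. Replicates 3 to 6 gave 7 and replicates 1 and 2 gave 8. Of 29 alternatives, the ribosomal protein, mitochondrially encoded, microtubule and presynaptic lists were called in 27, calcium and fibroblast in 26 (the latter was too small to test at a mean FPKM of at least 5), cell cycle in 24, histones in 20, immediate early in 18, interneuron in 17, astrocyte in 10, and p53 and nuclear-retained in 8 each. The difference in mitochondrial share was 8.68 to 17.4 percentage points with 1 library left out. With the replicate block it was 14.3 (exact sign-flip p = 0.0625), and within replicates 1 and 2 it was 19.8 (exact permutation p = 1, with 6 arrangements). The difference in genes detected did not pass in any setting, and turned to -137.3 without axonal replicates 1 and 2 and somatodendritic replicate 4. The planned filter on FPKM status was not run, since all values carried the status OK. At the depths, spread and sample size of these libraries, 8% of simulated 4-fold changes were recovered. The limits set by depth, spread and sample size were not tested apart.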

Other observations

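The tests in this part were chosen after the result was seen, except the comparison of the ribosomal protein list with matched lists.

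Chance cannot be excluded for the count of called genes, since 15 of 100 splits of the 12 libraries, drawn from 462, gave at least 1 called gene, the real value. The highest of the other splits gave 11, and it put replicates 1 and 2 of both compartments with somatodendritic replicates 3 and 6, which largely follows the sets of replicates that differ in short non-coding RNA and points to a structure of the samples. Within replicates 3 to 6 the compartments gave 7 called genes. For the 13 lists called with the preset correlation, 1 of 100 splits, the real one, gave as many. These splits argue against chance for the count with all 12 libraries and the preset correlation, and for no other. They do not exclude it, since only 100 of 462 splits were drawn. Over the other splits the median was 3 called lists, so camera with the preset correlation also called lists where the compartments were mixed. The margin was 1 list over the highest other split, which gave 12. That split set axonal replicates 1, 3 and 6 and somatodendritic replicates 1, 2 and 6 against the rest. The splits did not keep the sets of replicates, and they were not drawn for the other settings, of which an estimated correlation and fry gave 0 lists, leaving out 1 library gave 7 to 12, replicates 3 to 6 gave 7 and the batch term gave 10.

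Axonal replicates 1 and 2 listed 9.14 and 19.4% of olfactory and vomeronasal receptor genes above 0, against 0 to 0.77% in the other 10 libraries. Greater depth is argued against, since receptor genes above 0 per 100000 reads came to 17.96 and 73.96 in these 2 libraries against at most 5.04 in the others. Genomic DNA in these libraries may be a source. Among 621 other genes that motoneurons are not known to use (keratin-associated, defensin, cornified envelope and immune receptor segment genes), 3.38 and 5.96% were above 0 in these libraries against at most 0.32% in the others. Axonal replicate 3 gave the highest of these other values, at 0.77%, 5.04 and 0.32%. No biological explanation was tested.

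The ribosomal protein list was higher in axonal libraries, with a median log2 fold change of 0.595. Genes of like exon length and mean level did not show this rise. The median of 10000 random lists matched on both was 0.014, with 95% of them between -0.107 and 0.176, and the list lay at percentile 100. Exon length here joined the exons of all annotated transcripts of a gene (median 1781 bases in the list) and can exceed that of the message. Short messages as a cause therefore stay open. The random lists drew each gene singly, so their range leaves out correlation between genes. Axonal replicates 1 and 2 as the source are argued against, since without them the relative median was 0.6, against 0.42 with all libraries. The compartment itself stays open and untested, and so does a correlation between these genes, with which the list was not called.

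The fibroblast and meningeal list, which holds contractile and matrix genes, was called higher in axonal libraries with the preset correlation. It was not called with an estimated correlation (camera adjusted p = 0.203) or with fry (adjusted p = 0.053). Axonal replicates 1 and 2 are argued against, since without them the relative median was 1.27, against 1.03 with all libraries. A larger share of all non-neuronal cells stays open. Astrocyte markers had a mean log2 fold change of -0.32 against 1.28 for this list (permutation p = 0.00016 over genes, which are not independent replicates), but these lists were compared because they had been called in opposite directions. The microglia and Schwann cell lists had relative medians of 0.76 and 0.49 without axonal replicates 1 and 2, against -0.30 for the astrocyte list. Collagen-producing fibroblasts stay open as well. Col1a1, Col1a2 and Col3a1 averaged 1.4% of Fn1 in the axonal libraries, but these genes lie near the floor and no table here gives the ratio such cells would have. Another contractile cell type on the axonal side and the compartment itself stay open and untested.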
